A study of Mus musculus with 4 samples.

How the data were processed

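RNA of the frontal cortex of male ddY mice, an outbred laboratory stock, was measured on 4 dual-colour Agilent mouse oligonucleotide arrays, 1 for each of 4 antipsychotic drugs. Per the labels, mice aged 13 weeks received 1 intraperitoneal injection a day for 28 days, of chlorpromazine or thioridazine at 25 mg/kg, olanzapine at 1.25 mg/kg or quetiapine at 18.75 mg/kg. RNA of vehicle-injected mice carried cyanine 3 and RNA of drug-injected mice cyanine 5 on every array, so no dyes were swapped. How many mice gave RNA to an array, and whether 1 vehicle RNA served on all 4, is not given in the sources used here. Per the labels, the images were read with Agilent Feature Extraction 7.1, with a rank consistency filter and LOWESS dye normalisation.

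The deposited values were read as the log10 ratio of the 2 channels, which is likely drug over vehicle. That reading rests on the dyes in the labels and on the software's own log ratio being log10 of red over green; neither scale nor direction is stated for the table itself. The authors' centring is also unstated: the median of the deposited log10 values was 0 on the chlorpromazine, thioridazine and quetiapine arrays and 0.00376 on the olanzapine array. The table holds no signal intensities, so no filter on dim probes was possible, random gene lists could not be matched on expression, and the distance of a spot from background is unknown. Precision is limited by the number of arrays.

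The table has 22393 features. The platform annotation gave 18218 of them 1 gene symbol and 16 several symbols, and 4159 were unnamed here. By Entrez identifier, 18175 features took the symbol of the current RefSeq table (assembly GRCm38.p6, used for names only), and 43 kept the platform's name. Features with several symbols were left out. Values of exactly 0 were treated as not measured; they numbered 367 on the chlorpromazine, 484 on the thioridazine, 198 on the olanzapine and 594 on the quetiapine array. Ratios were converted to log2, and the features of a gene were averaged. This gave 16504 genes, of which 1193 had 2 or more features and 354 had features that differed by 1 log2 unit or more on an array. Tests used the 16139 genes measured on all 4 arrays.

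No drug has a second array, so no drug was tested alone. Genes at least 2-fold from vehicle were counted on each array. Both tests were run with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The first set the mean log2 ratio of the 4 arrays against 0, with the 4 drugs standing as replicates of treatment; it leaves out the spread between vehicle mice and cannot separate a dye bias from a shared change. The second set the phenothiazines (chlorpromazine and thioridazine) against the drugs with an azepine ring (olanzapine and quetiapine), 2 arrays each; a dye bias common to the arrays cancels there. The arrays are not labelled as replicate animals, so p-values measure the spread between these 4 arrays. Profiles were compared by Pearson r and Spearman rho across genes, and 100 simulations of unchanged drugs against 1 shared vehicle, with equal noise in drug and vehicle, gave the r that sharing alone produces. A further 100, chosen after seeing the data, gave each simulated array its own observed values by rank (mean r 0.458) and served for the shares of genes with 1 sign, the limma counts and the overlaps. They assume the same noise for every gene.

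Tested were 25 gene lists with at least 5 measured members, with limma's camera at a preset correlation of 0.01. Alternatives were fry and camera with an estimated correlation. The latter draws on the residual degrees of freedom, 3 in the shared change and 2 in the class difference. A call lost there may therefore reflect low power. On single arrays a list's median was placed among 10000 random lists of its size. Genes named for a test are the 10 highest and 10 lowest log2 values among called genes that had 1 sign on all arrays, or whose 2 arrays of a class lay above both of the other; open places were filled by the smallest unadjusted p and are described as not passing. Per array, the 5 highest and 5 lowest ratios are named. For lists, the 2 members with the largest mean and the 2 with the largest class difference are named, with any called member. Clone-style names were left out. Groups, tests, lists, this rule and the following alternatives were fixed before the data were examined: another log base, zeros kept, every feature its own row, arrays centred or scaled, each array left out, robust or no moderation, a fold minimum, Spearman rho, and genes 1.5-fold on an array. Alternatives without the receptor genes, over the list genes alone and without Mt1 and Mt2, 3 added gene lists and the tests of explanations were chosen after seeing the data. The position and haemoglobin tests in the closing section were revised after a first run, to skip unnamed features and to take in every measured haemoglobin gene. Their rules were later narrowed, so that the first excludes position only where the correction moves a correlation, and the second excludes blood only where both azepine arrays lie below both phenothiazine arrays; neither explanation was excluded then. The scaling of arrays to one median absolute log ratio was corrected after a first run, which had divided each array by its signed median, a value close to 0.

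The fits were tested on simulated data with the spread of the 16139 real genes and 200 changed genes, in 10 runs. For the shared change 66.4% of genes changed by 1 log2 unit were recovered, 90.7% at 2 and 96.1% at 3. For the class difference the shares were 0.299%, 43.0% and 60.5%. Of a mean of 179.1 calls in the shared change 10.4 were false, and of 71 in the class difference 2.1. All 10 shifted lists and 0 of 90 unshifted lists were called in each comparison. Arrays were drawn independently there, with no vehicle or dye bias in common, so these shares do not cover arrays that have one. Genes were also drawn independently, and lists were shifted by more than the median of any list called in the real data. The result therefore does not show how often lists with correlated members are falsely called. The glucocorticoid list, for one, had an estimated correlation of 0.34 in the shared change.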

Results

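Gene expression in the mouse frontal cortex was compared between each of 4 antipsychotic drugs and vehicle, with the aim, from the study's title, of classifying the drugs by expression. Each drug has 1 array, on which drug and vehicle RNA were hybridised together, so each value is a ratio with no replicate for that drug. Between 16240 and 16435 genes had a ratio on an array. The ratios were read as log10, which is likely but not stated; if they were log2 already, every fold below would be smaller. Drug over vehicle is also the likely direction and not a stated one; if it were the reverse, every rise and fall and every count above and below vehicle would change places. The standard deviation of the log2 ratios over genes was 0.33 with chlorpromazine, 0.47 with thioridazine, 0.59 with olanzapine and 0.43 with quetiapine. For 48 accessions spotted 10 or more times, the median standard deviation between spots was 0.06, 0.16, 0.16 and 0.10 in the same order, which is the technical spread within an array only.

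On the chlorpromazine array, 130 genes were at least 2-fold above vehicle and 147 at least 2-fold below. The highest log2 ratios were those of Sdhd, a subunit of succinate dehydrogenase, at 4.72, the lymphocyte activation antigen Cd69 at 4.02, Ocel1 at 2.87, Dnajc27 at 2.14 and Bbs1, a gene of the primary cilium, at 2.02. The lowest were the desmosomal gene Pkp1 at -4.05, the lysosomal transcription factor Tfeb at -3.22, the innate immune receptor Tlr2 at -2.69, the vomeronasal receptor Vmn1r15 at -2.66 and Tent4b at -2.63. Among gene lists, astrocyte markers had a median log2 ratio of 0.21, and glucocorticoid-responsive genes and endothelial and pericyte markers both had 0.19, at the 99.93th, 99.94th and 99.96th percentiles of random lists. Oxidative phosphorylation genes had a median of -0.13 (percentile 0.01). Microglia and macrophage markers had a median of -0.24 (percentile 0.07), with 13 of 15 members below 0. Cytosolic ribosomal protein genes had a median of -0.12, with 48 of 62 members below 0.

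On the thioridazine array, 323 genes were at least 2-fold above vehicle and 415 below. Pirb, an inhibitory receptor of myeloid cells, was highest at 3.27, followed by Metap1d at 2.92, the transcription factor Sp5 at 2.90, Ly6g6e at 2.83 and the interferon-inducible chemokine Cxcl10 at 2.72. The lowest were Zfp36l2, an RNA-binding protein of messenger RNA decay, at -6.28, Ak8 at -4.05, Tbx3 at -3.75, the replication licensing gene Cdc6 at -3.55 and the angiotensin receptor Agtr1b at -3.55. Microglia and macrophage markers had a median of 0.32 (percentile 99.95), and heat shock and unfolded protein response genes of -0.37, below all 10000 random lists, with 21 of 25 members below 0.

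The olanzapine array, at the lowest dose in mg/kg and with the widest spread, had the most genes 2-fold from vehicle, 763 above and 547 below. With the arrays scaled to one spread olanzapine still had the most, 1041, but chlorpromazine, which had the fewest before, rose from 277 to 609, against 563 with thioridazine and 549 with quetiapine. The highest were the transporter Abcc1 at 4.35, Tedc1 at 3.99, the sodium channel Scn9a at 3.89, Tex29 at 3.82 and Mptx1 at 3.75. The lowest were Sdhd at -4.05, opposite in sign to the other 3 arrays, Cdx4 at -3.39, Slc26a3 at -3.36, the odorant receptor Olfr613 at -3.29 and Rad51ap1 at -3.17. Immediate early genes, which respond to neuronal activity, had a median of 0.32 (percentile 99.98), with 20 of 25 members above 0. Glucocorticoid-responsive genes had a median of 0.34 (percentile 99.97). Heat shock and unfolded protein response genes had a median of -0.30 (percentile 0.02), red blood cell genes of -0.65 (percentile 0.03), and genes of GABA synthesis, transport and receptors of -0.36 (percentile 0.09).

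On the quetiapine array, 233 genes were at least 2-fold above vehicle and 375 below. The calprotectin subunits S100a9 and S100a8, abundant in neutrophils, were highest at 5.81 and 5.02. Sdhd followed at 4.62, then the acute-phase genes Saa3 at 4.12 and Hp at 3.49. The lowest were Trim65 at -3.69, Cd226 at -2.76, Cenpo at -2.74, Papln at -2.63 and the activity-regulated gene Arc at -2.56. Glucocorticoid-responsive genes had a median of 0.85, above all 10000 random lists, and 8 of 18 were at least 2-fold above vehicle. Heat shock and unfolded protein response genes had a median of -0.57, with 23 of 25 below 0. Immediate early genes had a median of -0.30 (percentile 0.02), on the other side of 0 from the olanzapine array, and the difference between these single arrays could not be tested. The array counts have no replicate check, and at a threshold of 1.5-fold they came to 1131, 2186, 2865 and 2050 genes for chlorpromazine, thioridazine, olanzapine and quetiapine.

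**Figure D1:**
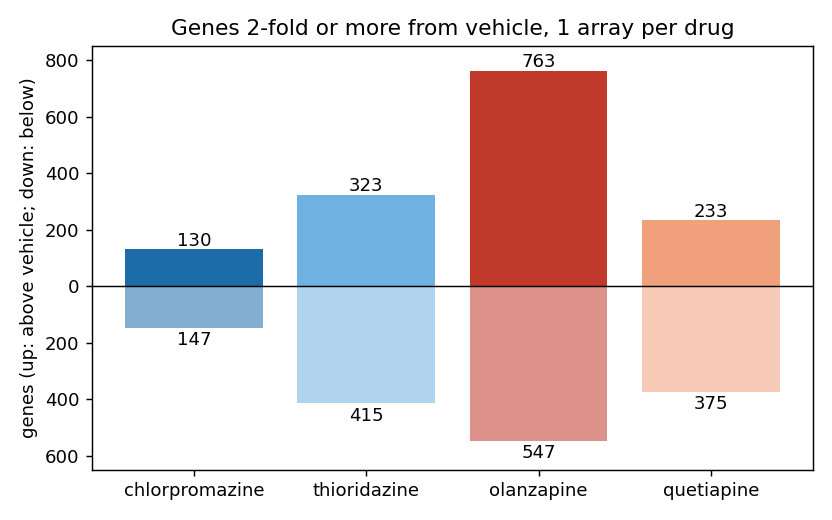
Number of genes at least 2-fold above vehicle (upper bars) and below vehicle (lower bars) on the single array of each drug. The olanzapine array has 763 and 547 such genes and the chlorpromazine array 130 and 147.

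The change shared by the 4 drugs was asked by setting the mean of the 4 arrays against 0. With limma, 24 of 16139 genes passed, 5 higher and 19 lower than vehicle. Having 1 sign on 4 of 4 arrays was a condition for naming a gene here and is not a result. Of the 5 called increases the largest was in Afm, a vitamin E-binding plasma protein, with a log2 mean of 1.31 (SE 0.10, limma adjusted p = 0.0347). Lss, lanosterol synthase of the cholesterol pathway, rose by 1.23 (SE 0.07, limma adjusted p = 0.0242). Hsd11b2, an enzyme that inactivates glucocorticoids, rose by 1.15 (SE 0.09, limma adjusted p = 0.0499), Fam221a by 0.98 and the ubiquitin ligase adaptor Klhl15 by 0.87. The call of Hsd11b2 ended with exact zeros kept (limma adjusted p = 0.0627), with every feature on its own (0.0526), with arrays centred on the median (0.0518) and with robust moderation (0.0560). The genes next in order did not pass: Nkx3-2 had a mean of 0.93, Acy1 of 0.85, the ciliary gene Tekt1 of 0.96, Styxl1 of 1.06 and Fgl2 of 0.87.

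Among the called genes named here, Arhgap32 fell most, with a mean of -1.99 (SE 0.13, limma adjusted p = 0.0311). The vomeronasal receptor Vmn1r220 was at -1.95, the oocyte transcription factor Figla at -1.87, the neurokinin B receptor Tacr3 at -1.79 and the muscle gene Lmod2 at -1.74. Nxf2 was at -1.57, Pof1b at -1.55, Qrfprl at -1.46, the lysyl oxidase family gene Loxl4 at -1.45 and Fnbp1l at -1.42. Each of these genes had 1 feature. All 4 arrays had 1 sign for 40.3% of genes, against 12.5% for independent arrays and 40.0% for unchanged drugs simulated against 1 shared vehicle. With limma 4223 genes had an unadjusted p under 0.05, against 807 for independent arrays and a mean of 4078 in those simulations, in which 0 to 11 genes passed against the observed 24. These shares and counts are therefore close to what a shared vehicle gives with no drug effect, apart from the number of genes passing. No gene passed with limma when 1 array was left out; the genes with an unadjusted p under 0.05 then numbered 3533 without chlorpromazine, 2489 without thioridazine, 3110 without olanzapine and 3095 without quetiapine. The count was also 0 with an ordinary t statistic (3548). With the arrays scaled to one spread 62 genes passed, 15 of them higher, but only 12 of the 24 were among them; Afm (limma adjusted p = 0.0728), Klhl15 (0.0671), Fam221a (0.0600), Lmod2 (0.0567) and Fnbp1l (0.0567) did not pass then, while Tekt1 and Fgl2 did (both 0.0458). Odorant, vomeronasal and taste receptor genes, which have little transcription in cortex, correlated between arrays with a mean r of 0.335, against 0.371 for the other genes.

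**Figure D2:**
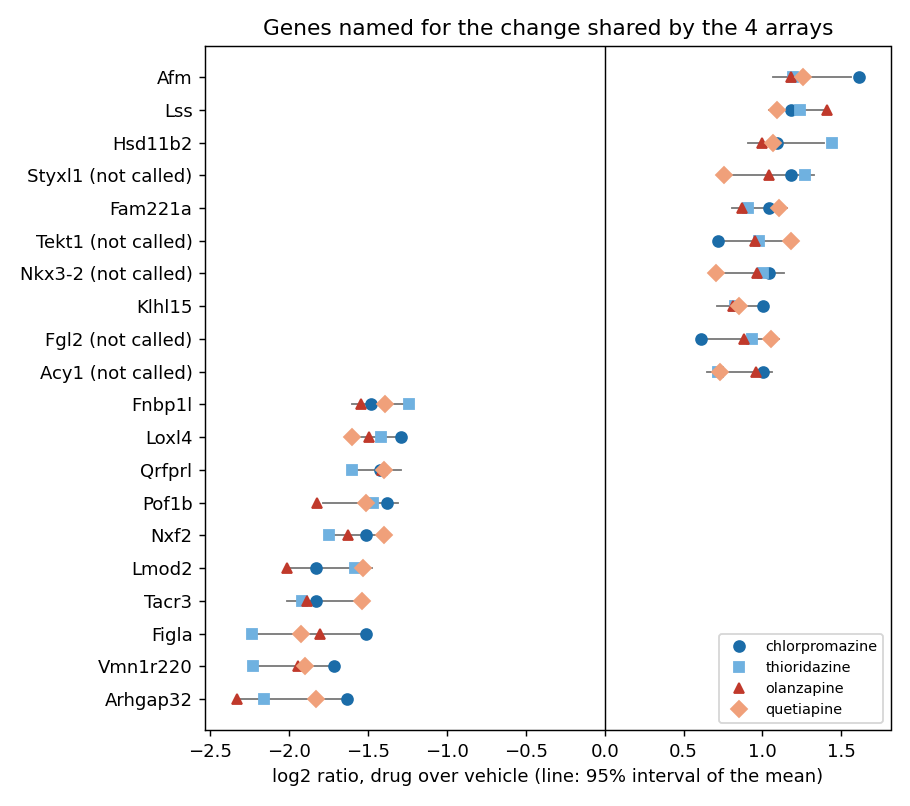
Log2 ratio of drug over vehicle for the 20 genes named for the shared change, 1 point per array, with the 95% interval of the mean of the 4 arrays as a line. The 15 called genes and the 5 marked as not called were named only if they had 1 sign on every array.

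Of 25 gene lists, 5 passed in the shared change with limma's camera. The test takes the arrays as independent replicates. A list that was high or low in a vehicle RNA common to the arrays, or biased between the dyes, could therefore pass with no drug effect. The simulations of a shared vehicle were not run for lists. The falls and rises of lists given here are thus changes of ratio and may not be drug effects. Heat shock and unfolded protein response genes fell (median -0.33, camera adjusted p = 0.00025, and adjusted p = 0.735 with an estimated correlation). The fall was not seen with chlorpromazine, where the list's median was -0.02 (percentile 28.69 of random lists). Of 25 members 21 had a mean below 0, 0 passed over all genes (13 at an unadjusted limma p under 0.05), and 8 were lower when adjusted over the list alone. The chaperones Hspa1a and Dnajb1 had means of -0.93 (SE 0.33) and -0.77 (SE 0.17). Proteasome subunits fell (median -0.14, camera adjusted p = 0.0082, and adjusted p = 0.735 with an estimated correlation), with 27 of 31 means below 0, including Psmc5 at -0.47 and Psmd13 at -0.28. Of these 31 subunits 0 passed over all genes or adjusted over the list alone, and 8 had an unadjusted limma p under 0.05. Over all genes 4223 of 16139 had such a p, a similar share, so this count sets the subunits apart from no other genes. Genes of cholesterol synthesis and SREBP targets fell (median -0.19, camera adjusted p = 0.0226, and adjusted p = 0.735 with an estimated correlation), with 20 of 26 means below 0. In that list 1 gene passed over all genes, and it was Lss, which was higher; adjusted over the list alone, 7 were lower and 1 higher. The sterol demethylase Cyp51 had a mean of -0.63 (SE 0.09).

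Oxidative phosphorylation genes fell by a small amount (median -0.07, camera adjusted p = 0.0446, and adjusted p = 0.909 with an estimated correlation), with 42 of 59 means below 0. With olanzapine their median was 0.03 (percentile 65.48 of random lists), on the other side of 0. Of these 59 genes 0 passed over all genes or adjusted over the list alone. An unadjusted limma p under 0.05 was found for 9, a smaller share than the 4223 of 16139 over all genes. Cox5a had a mean of -0.53, and Sdhd, at 2.0 (SE 1.62), lay on the other side of 0. Glucocorticoid-responsive genes rose (median 0.30, camera adjusted p = 0.0226, and adjusted p = 0.735 with an estimated correlation), with 15 of 18 means above 0. With thioridazine their median was -0.04 (percentile 31.72 of random lists). Of these 18 genes 0 passed over all genes or adjusted over the list alone, and 6 had an unadjusted limma p under 0.05, against 4223 of 16139 over all genes. The transcription factor Cebpd had a mean of 1.60 (SE 0.31) and the metallothionein Mt2 of 1.29 (SE 0.36). With an estimated correlation 0 lists passed and 1 had an unadjusted p under 0.05. Fry called 1 list, cholesterol synthesis (fry adjusted p = 0.0299), and its test for change in either direction called 15. Without the quetiapine array 3 lists passed, and the glucocorticoid list was at a camera adjusted p of 0.0793; without the olanzapine array the cholesterol list was at 0.0573, and oxidative phosphorylation was lost without the chlorpromazine array at 0.15, without thioridazine at 0.243 and without quetiapine at 0.121. Without the receptor genes, a setting chosen after seeing the data, it was at 0.0676.

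The other lists did not pass in the shared change. Dopamine receptors and signalling genes, which hold the main target of these drugs, had a median of 0.06 (camera adjusted p = 0.934); adjusted over the list alone 2 of 19 were lower, of which Ddc, the enzyme that makes dopamine from its precursor, had a mean of -0.84 (SE 0.09) and lay below 0 on 4 of 4 arrays. Serotonin receptors and transport had a median of 0.07 and a mean of -0.02 (camera adjusted p = 0.854), with 1 of 15 lower adjusted over the list alone, Htr2b at -0.75 (SE 0.09). Endothelial and pericyte markers had a median of 0.12 (camera adjusted p = 0.174, and 0.0291 without olanzapine), with 3 of 18 higher adjusted over the list alone; the glucose transporter Slc2a1 had a mean of 1.05 and Vwf of 0.91. Microglia and macrophage markers had a median of 0.19 (camera adjusted p = 0.21, and 0.00708 without chlorpromazine). Markers of cortical layers had a median of 0.07 (camera adjusted p = 0.94); 3 of 19 were lower and 1 higher adjusted over the list alone, and the higher, Ccn2, a marker of the deepest layer, had a mean of 0.83 (SE 0.12). Immediate early genes had a median of 0.04 but a mean of -0.14 (camera adjusted p = 0.94).

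**Figure D3:**
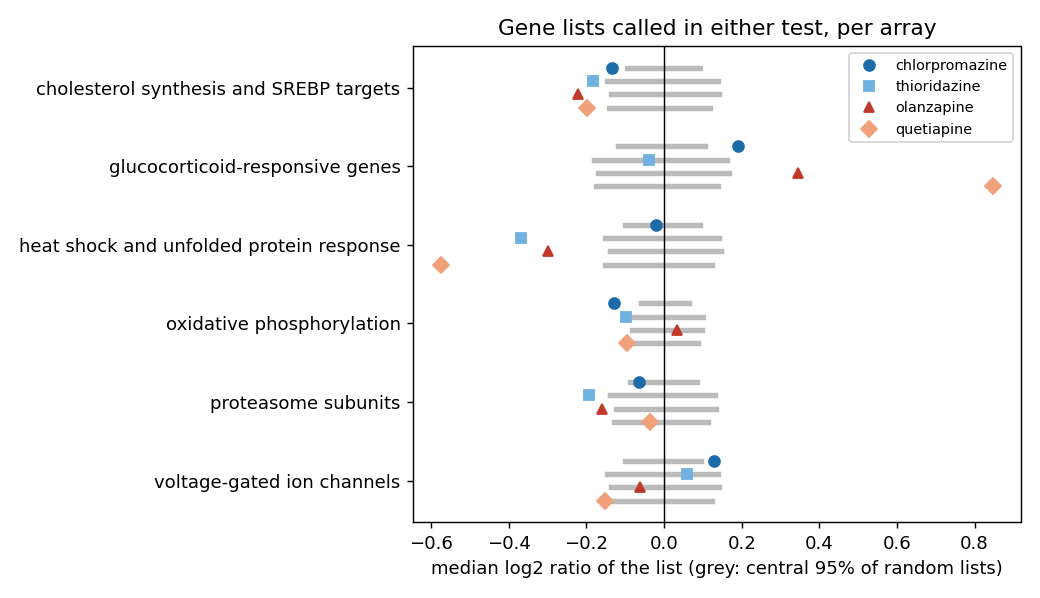
Median log2 ratio of the 6 gene lists called in either test, 1 point per array, with the central 95% of random lists of the same size in grey. Glucocorticoid-responsive genes reach 0.85 with quetiapine, and heat shock and unfolded protein response genes -0.57.

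The chemical classes were compared next. Chlorpromazine and thioridazine share the phenothiazine ring and were given at 25 mg/kg. By contrast, olanzapine, a thienobenzodiazepine, and quetiapine, a dibenzothiazepine, were given at 1.25 and 18.75 mg/kg. Per the labels the doses were set to be therapeutically equivalent, but class and dose in mg/kg differ together. No gene passed with limma, and 458 of 16139 had an unadjusted p under 0.05, against 807 expected. Pairing chlorpromazine with olanzapine instead gave 550 such genes, and pairing it with quetiapine gave 1408, each with 0 passing. For the classes an ordinary t statistic also called 0 (575). The number at an unadjusted p under 0.05 was 921 without olanzapine and 1332 without quetiapine, again with 0 passing. The median 95% interval reached 0.50 log2 units to each side, and in simulated data 0.299% of class differences of 1 log2 unit and 43.0% of those of 2 were recovered, so many differences of these sizes would go undetected. The genes named here therefore did not pass, all with a limma adjusted p above 0.99. Ngp, a neutrophil granule gene, had a phenothiazine mean of 0.07 and an azepine mean of 3.27, a difference of -3.19 (95% interval -3.81 to -2.57). Mt2 had means of 0.51 and 2.06, a difference of -1.55 (95% interval -1.99 to -1.11). Differences below 0 were also found for Tnfrsf26 at -1.45, the chemokine Ccl17 at -1.32, the autophagy kinase Ulk1 at -1.08, Opn5 at -1.04, Brinp1 at -0.91, Olfr703 at -0.91, Gsdma2 at -0.89 and the haematopoietic gene Ms4a3 at -0.79.

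On the other side, the nuclear import receptor Ipo9 had a phenothiazine mean of 1.67 and an azepine mean of 0.09, a difference of 1.59 (95% interval 1.15 to 2.03). Olfr212 differed by 1.25, the dynein chain Dync1li2 by 1.16, Zfp292 by 1.14, nucleolin (Ncl) by 1.07, Rnd2 by 1.06, Rpusd4 by 0.93, Lamtor2 by 0.88, the postsynaptic scaffold gene Homer2 by 0.87 and the axon guidance gene Sema3a by 0.84. The 2 features of Dync1li2 differed from each other by up to 1.30.

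With camera, 4 of 25 lists differed between the classes. Glucocorticoid-responsive genes were lower with the phenothiazines (median difference -0.44, camera adjusted p = 3.07e-05, and adjusted p = 0.865 with an estimated correlation), with 15 of 18 differences below 0. The medians were 0.19 with chlorpromazine, -0.04 with thioridazine, 0.34 with olanzapine and 0.85 with quetiapine. In the same order, 2 lists chosen after seeing the data, without the members that prompted them or had been looked at by then, had medians of 0.07, 0.29, 0.40 and 0.32 for neutrophil granule genes and 0.14, 0.36, 0.43 and 0.63 for acute-phase and cytokine-response genes. Over all genes 0 passed (3 at an unadjusted limma p under 0.05), and 1 passed adjusted over the list alone, Mt2; the difference of Mt1 was -0.92 (SE 0.23). Heat shock and unfolded protein response genes were higher with the phenothiazines (median difference 0.16, camera adjusted p = 0.00282, and adjusted p = 0.92 with an estimated correlation), 20 of 25 being above 0. The medians were -0.02 with chlorpromazine, -0.37 with thioridazine, -0.30 with olanzapine and -0.57 with quetiapine, so the single arrays did not separate by class. Members included Hspa5 at 0.90 (SE 0.37) and Canx at 0.60 (SE 0.16). Voltage-gated ion channels were higher (median difference 0.18, camera adjusted p = 0.00282, and adjusted p = 0.865 with an estimated correlation), 19 of 24 being above 0, with Kcnip2 at 0.64 (SE 0.14) and Kcnd2 at 0.54 (SE 0.18), and had medians of 0.13 and 0.06 with the phenothiazines and -0.06 and -0.15 with olanzapine and quetiapine. Oxidative phosphorylation genes were lower (median difference -0.09, camera adjusted p = 0.00443, and adjusted p = 0.92 with an estimated correlation), 48 of 59 being below 0, while Sdhd differed by 3.43 (SE 3.19). Their medians were -0.13 with chlorpromazine, -0.10 with thioridazine, 0.03 with olanzapine and -0.10 with quetiapine. In the heat shock, ion channel and oxidative phosphorylation lists 0 members passed over all genes or adjusted over the list alone; 1, 3 and 0 had an unadjusted limma p under 0.05.

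With an estimated correlation 0 lists passed and 0 had an unadjusted p under 0.05. Fry called 0 lists, with 1 at an unadjusted p under 0.05. With every feature on its own, genes of GABA synthesis, transport and receptors were called as higher with the phenothiazines (camera adjusted p = 0.0368, against 0.111 in the main setting). They were also among the lists that passed without quetiapine. Without quetiapine 3 lists passed, and the camera adjusted p was 0.276 for the glucocorticoid list, 0.53 for heat shock and 0.204 for ion channels; without chlorpromazine 2 lists passed, and it was 0.466 for heat shock and 0.408 for ion channels; oxidative phosphorylation was at 0.203 without thioridazine and 0.555 without olanzapine. Red blood cell genes, markers of blood in the tissue, had a median of -0.65 with olanzapine and 0.32 with quetiapine, so these arrays of 1 class lay on opposite sides. Immediate early genes did not differ past the threshold (camera adjusted p = 0.506, and 0.954 with an estimated correlation, which was 0.69). They were higher with the phenothiazines without olanzapine and lower without quetiapine, settings that leave 1 array in a class. Microglia and macrophage markers were at a camera adjusted p of 0.25, and at 0.942 with an estimated correlation, which was 0.72. Their medians were -0.24 with chlorpromazine, 0.32 with thioridazine, 0.08 with olanzapine and 0.16 with quetiapine. Without thioridazine the class difference rests on chlorpromazine alone.

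**Figure D4:**
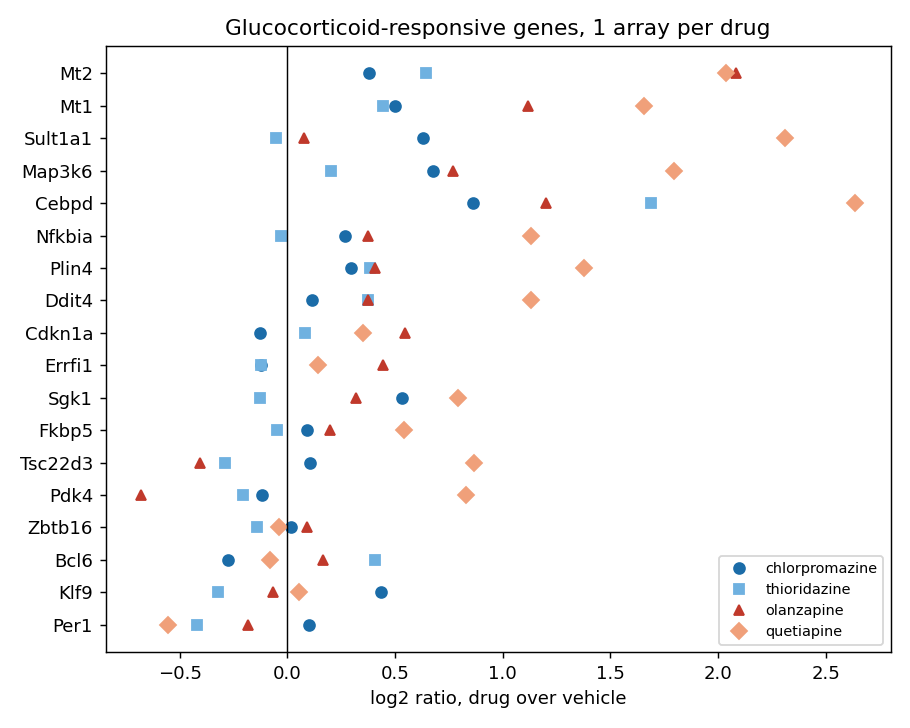
Log2 ratio of drug over vehicle for the 18 measured glucocorticoid-responsive genes, 1 point per array, ordered by the difference between the classes. Mt2 lies at 0.38 and 0.64 with the phenothiazines and at 2.08 and 2.04 with olanzapine and quetiapine.

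The grouping of the drugs by profile was described with correlations across genes, which are not independent replicates. Over all genes thioridazine and olanzapine were most alike (r = 0.520, Spearman rho = 0.567), followed by thioridazine and quetiapine at 0.403 and chlorpromazine and quetiapine at 0.387. The phenothiazines correlated at 0.340 and the azepine drugs at 0.309, and chlorpromazine and olanzapine were lowest at 0.260. Over the 543 genes of the gene lists, a setting chosen after seeing the data, the order changed: thioridazine and quetiapine were at 0.492, chlorpromazine and quetiapine at 0.485, the phenothiazines at 0.374, and thioridazine and olanzapine at 0.297. The mean r within classes was 0.324 and between classes 0.393. The standard deviation of the 6 coefficients was 0.090, but they share arrays, so it does not test this gap. The difference, -0.068, was -0.155 without chlorpromazine and -0.017 without thioridazine. Pairing chlorpromazine with quetiapine and thioridazine with olanzapine gave the higher within-pair mean, 0.454 against 0.328 between pairs. The mean r over the 6 pairs was 0.370; unchanged drugs against 1 shared vehicle gave 0.500 in simulation, and the mean covariance was 0.0728 against 0.0965 simulated. Whether the vehicle was shared is not given in the sources used here, so part or all of this mean resemblance may come from it. In the simulations that gave each array its own values by rank, thioridazine and olanzapine had an r of 0.452, below the observed 0.520. Each other pair lay below its simulated r. These simulations assume equal noise in drug and vehicle.

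Chlorpromazine and thioridazine, both given at 25 mg/kg, differed by at least 2-fold for 667 genes, 371 of them higher with chlorpromazine. They had 31 genes in common 2-fold above vehicle, against 2.29 for independent lists and 26.2 for unchanged drugs simulated against 1 shared vehicle, and 47 below, against 2.90 and 30.0. Olanzapine and quetiapine, at different doses, differed for 1337 genes, with 71 in common above vehicle, against 10.1 for independent lists and 71.9 simulated, and 68 below, against 9.90 and 72.8. Thioridazine and olanzapine had 167 in common above, against 13.1 and 87.2, and 114 below, against 10.3 and 75.3. Part of any excess may come from a shared vehicle. These counts compare single arrays and have no test. They also depend on the spread of each array, which was widest with olanzapine.

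**Figure D5:**
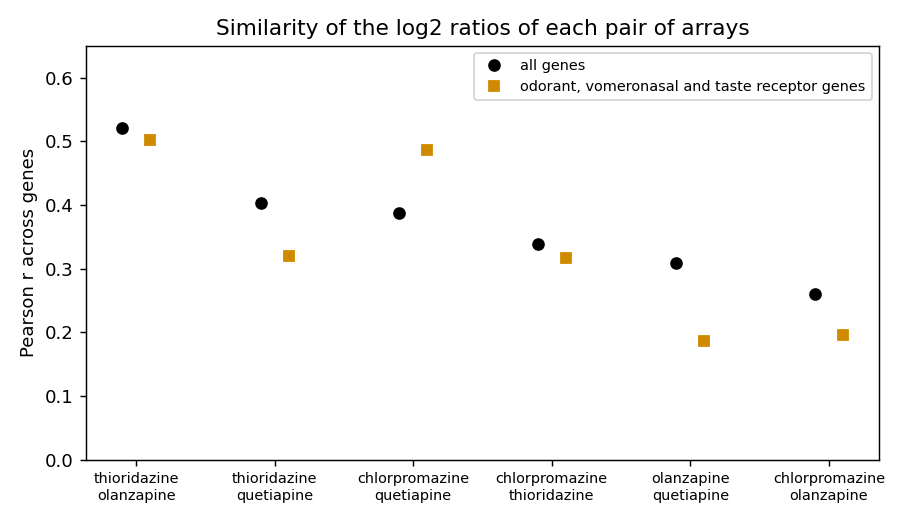
Pearson r across genes for each pair of arrays, over all 16139 genes (circles) and over 838 odorant, vomeronasal and taste receptor genes (squares). Thioridazine and olanzapine are highest in both, at 0.520 and 0.503.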

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

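Of the tests in this part, those of 1 vehicle RNA and of blood, and the settings without receptor genes, over the list genes alone or without Mt1 and Mt2, were chosen only after the values they rest on had been seen.

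Between the chemical classes 4 gene lists differed by camera's test of the difference: glucocorticoid-responsive genes (median difference -0.44), heat shock and unfolded protein response (0.16), oxidative phosphorylation (-0.090) and voltage-gated ion channels (0.18). None of these calls held with an estimated correlation, where the camera adjusted p was 0.865 for the glucocorticoid and ion channel lists and 0.92 for the others. For the ion channel list the estimate was 0.007, below the preset 0.01, so correlation between members did not end its call.

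Some genes named for the class difference had both arrays of a class on one side of vehicle and both of the other class on the opposite side; their difference was tested and did not pass. Values above 0 were those of Zfp292 (1.14), Ncl (1.07), Homer2 (0.87), Lamtor2 (0.88), Dync1li2 (1.16) and Rnd2 (1.06), and below 0 those of Tnfrsf26 (-1.45), Opn5 (-1.04) and Olfr703 (-0.91).

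Some genes named for a single array were at least 2-fold from vehicle in opposite directions on different arrays; these differences were not tested, as each drug has 1 array. Sdhd was at 4.72 with chlorpromazine, 2.70 with thioridazine, 4.62 with quetiapine and -4.05 with olanzapine. Zfp36l2 was at -6.28 with thioridazine and 3.08 with olanzapine. Tfeb was at -3.22 with chlorpromazine and 3.15 with quetiapine. Cd69 was at 4.02 with chlorpromazine and -1.26 with quetiapine. Vmn1r15 was at -2.66 with chlorpromazine, 1.04 with thioridazine and 1.66 with olanzapine. Agtr1b was at -3.55 with thioridazine and 1.36 with olanzapine, Rad51ap1 at -3.17 with olanzapine and 1.11 with quetiapine, and Trim65 at -3.69 with quetiapine and 1.41 with olanzapine. Each of these genes rests on 1 feature.

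Outside the genes analysed, 483 of 4159 unnamed features were at least 2-fold below vehicle on all 4 arrays, or 11.6%, against 27 of 17760 named features with a value on every array, or 0.152%. Their median log2 ratio lay between -3.25 with chlorpromazine and -4.48 with thioridazine. What these features are is not given in the sources used here.

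A first pattern is that ratios resembled each other on all arrays, from which the shared calls come. A bias of dim probes between the dyes may account for much of it: receptor genes with little transcription in cortex had a mean r of 0.335 between arrays, against 0.371 for other genes. Without them 24 genes were called, 23 of them also called with them. Only 1 receptor gene was among the calls of the main setting, so leaving receptor genes out could hardly change the calls and does not test this bias. Noise of 1 vehicle RNA on all arrays cannot be told apart from this, since the observed mean r of 0.370 lies below the simulated 0.500 and sharing is not stated; 40.3% of genes had 1 sign on 4 arrays against 40.0% simulated, but the 24 genes called exceed the simulated mean of 0.94 and highest count of 11 in 100 runs, which assume equal noise for every gene. A response common to the 4 drugs, the biological explanation, stays open as untested, since no array has the dyes reversed.

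A second pattern is the closeness of thioridazine and olanzapine, across chemical classes, which held over all genes (r = 0.520) but not over the 543 genes of the gene lists, where their r of 0.297 lay below those of 3 other pairs. A trend along the feature number, taken for position, cannot be told apart: with a running median removed the excess of their r over the other pairs was 1.05 times as large, but the removal moved no r by over 0.00755 and so decides nothing. Feature numbers are also not stated to follow position. A bias of dim probes that these arrays share may contribute, since the pair also led among receptor genes, by 0.201 over the mean of the other pairs, with chlorpromazine and quetiapine close behind (0.503 and 0.487). A common effect of both drugs stays open and could not be tested with 1 array each.

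A further pattern is the lower level of glucocorticoid-responsive genes with the phenothiazines. It was not confined to metallothioneins: the 16 members other than Mt1 and Mt2 had a median difference of -0.38. That lies outside the -0.12 to 0.11 of the central 95% of random lists. Leaving out 2 of 18 members can hardly move a median of -0.44, so this describes the other members and tests little. Blood left in the tissue cannot be told apart. In the mean of 5 haemoglobin genes, the lower azepine array (olanzapine, -0.64) minus the higher phenothiazine array (thioridazine, 0.48) was -1.12. Quetiapine, on which the call rests, was at 0.19, between chlorpromazine at -0.08 and thioridazine. Red blood cell genes had a median of 0.32 with quetiapine. A split unrelated to class cannot be told apart, because another pairing of the 4 arrays gave the list a median difference 0.678 times as large, and the call ended without quetiapine (camera adjusted p = 0.276). A class effect, a dose effect, stress and an acute-phase response, whose list shares Nfkbia and Cebpd with this one, stay open as untested.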

How the results depend on the processing

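Alternatives without receptor genes, over preset-list genes only, and without Mt1 and Mt2 were chosen after seeing the data; all others were fixed before. The log base was not tested: read as log2, the counts of genes 2-fold from vehicle were 3 for chlorpromazine, 8 for thioridazine, 27 for olanzapine and 7 for quetiapine. At 1.5-fold they were 1131, 2186, 2865 and 2050. Scaling the arrays to one spread gave 609 for chlorpromazine, against 277, as it divided that array by 0.748; the other arrays stayed within 1.5-fold. For the shared change, 62 genes passed after that scaling, 12 of them among the 24, and 0 with an ordinary t statistic (3548 with an unadjusted p under 0.05). Without 1 array the count ranged from 0 to 0, with fewer arrays in the fit, a smallest adjusted p of 0.11 to 0.169 and 2489 to 3533 genes with an unadjusted p under 0.05. The other settings gave 21 to 24 calls. The class difference gave 0 calls in every setting run, with 385 to 1332 genes at an unadjusted p under 0.05; where 1 class kept 1 array, that array is assumed to vary like the rest. Lists called in the shared change ranged from 3 to 5 without 1 array (3 without quetiapine), with 0 by estimated correlation and 1 by fry. Lists called in the class difference ranged from 2 to 5 without 1 array (2 without chlorpromazine), with 0 by estimated correlation and 0 by fry; the latter tests whether a list moves at all and not against other genes. Immediate early genes reversed: not called in the class difference (camera adjusted p = 0.506), they were higher with the phenothiazines without olanzapine (0.000867) and lower without quetiapine (4.32e-07), in a range of 4.32e-07 to 0.764 without 1 array; these arrays lie on opposite sides of vehicle. The within-class minus between-class r stayed below 0 in every setting run, from -0.155 to -0.017. The log base, centring and scaling of arrays cannot change r, and the log base cannot change a p, so those settings are no check on them. Over single genes and lists, 1097 comparisons with an alternative kept the side of the threshold, or for single arrays moved by less than the spread between spots, 114 lost a call, 10 gained one and 80 values on single arrays moved by more than that spread, with the direction kept. For losses of calls where no reason is given the cause was not tested. Signal over background is unknown.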

Other observations

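The genes below were chosen after their values were seen, and the lists of acute-phase, interferon and neutrophil genes were written then; only members whose values had not been looked at by then were tested, against bounds set before the test. The exception is Fgl2 of the acute-phase list, named for the shared change, whose values were seen before the test was run; the values without it were added after the result.

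Immediate early genes lay on opposite sides of vehicle with olanzapine and quetiapine. Quetiapine had Egr2 at -2.40, Egr1 at -1.98, Klf10 at -1.50 and Dusp6 at -1.02, alongside Arc at -2.56. Olanzapine had Ptgs2 at 1.25, Npas4 at 1.19, Junb at 0.98 and Fos at 0.82. The quetiapine array also had the lowest median of heat shock and unfolded protein response genes, -0.57, and the highest of glucocorticoid-responsive genes, 0.85.

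Among the highest ratios of the quetiapine array were acute-phase genes, which led to the hypothesis of a raised acute-phase and cytokine response in that sample. The 25 members not looked at when the list was written had a median log2 ratio of 0.63, at percentile 100 of random lists (0.54 and percentile 100 without Fgl2), with 19 of them above 0, among them Lrg1 at 1.68, Bcl3 at 1.52 and Cp at 1.19, while Steap4 was at -1.96. The median was lower but also above nearly all random lists on the other arrays: 0.14 with chlorpromazine (percentile 99.82, and 99.29 without Fgl2), 0.36 with thioridazine and 0.43 with olanzapine. Extreme percentiles were common: of the 25 fixed lists, those above and below the central 95% of random lists numbered 4 and 5 with chlorpromazine, 3 and 3 with thioridazine, 2 and 5 with olanzapine and 4 and 5 with quetiapine, and random lists leave out that members of a list can move together. The test is consistent with such a response in the quetiapine sample and does not show it to be particular to that drug. The list shares Nfkbia and Cebpd with the glucocorticoid list.

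Neutrophils in the quetiapine sample may be a source of S100a8 and S100a9, at 5.02 and 5.81. The 9 members of the neutrophil list not looked at before had a median of 0.32 with quetiapine, at percentile 99.74, with Pglyrp1 at 1.71 and Anxa1 at 1.19, while the receptors Csf3r, Cxcr2 and Ltb4r1 were at 0.11, 0.06 and -0.12. Among the abundant granule genes Ngp was at 3.27 (3.26 with olanzapine), Camp at 2.90 and Lcn2 at 2.43, but Elane was at 0.01 and Mmp8 at -0.11. The median was 0.40 with olanzapine (percentile 99.57) and 0.29 with thioridazine (percentile 99.1), so this too is not particular to quetiapine. The list shares 4 of its 25 genes with the acute-phase list, and other cells make several of these transcripts.

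A raised interferon response was a hypothesis for the thioridazine sample, from Cxcl10 at 2.72 and Ifi27l2a at 2.67. The 29 members not looked at before had a median of 0.24, at percentile 99.98, which is consistent with it, although Trim21, seen before, was at -2.94. The same members were at 0.17 with quetiapine (percentile 99.81), -0.01 with olanzapine (percentile 37.1) and -0.10 with chlorpromazine (percentile 1.62). Differences between single arrays were not tested, and random lists were not matched on expression, so a bias that follows signal is not excluded in any of these 3 tests.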
